A study of Zea mays with 8 samples.

How the data were processed

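The series holds 8 RNA libraries from maize anthers, 2 for each of 4 groups: WT post-meiotic, hda108 post-meiotic, WT mitotic and hda108 mitotic. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into strand-specific libraries and sequenced on an Illumina HiSeq2500. The submitters' processing notes name CASAVA 1.8, Trimmomatic 0.33, TopHat2 2.0.13, SAMtools, Cufflinks and Cuffdiff 2.2.1 and the genome build B73 RefGen_v3, with no role or order. The authors deposited FPKM values, with 1 value per gene and group per the file headers. How the replicates were combined and how the groups were scaled to each other is not given in the sources used here.

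The values named for the homozygous genotype were taken as hda108, since the labels give hda108/hda108 as the only genotype beside WT. Because each group has 1 value, there is no estimate of the spread between replicates. The planned moderated test with limma, its adjusted p-values, the set test camera and Fisher's exact test of overlaps were not run, and no p-value is given. The fallback written before the data were examined was used instead: a gene counts as higher or lower when log2(FPKM + 1) differs by at least 2. Fold changes on that scale understate the change of low genes, so folds in the text are ratios of the FPKM themselves, and none is given against a group listed at 0.

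Genes with at least 1 FPKM in at least 1 group were kept, 24360 of 39604; the filter had been planned on 2 libraries, which the values do not separate. The authors' values were not scaled further in the main analysis. Differences were coded as hda108 minus WT, as mitotic minus post-meiotic, and for the fifth comparison as the mitotic genotype difference minus the post-meiotic one. The expected overlap of 2 sets of genes is the product of their sizes divided by the genes tested. It takes every gene as equally likely to be called, whatever its abundance. Depth is unknown because the values hold no counts, so no counting interval or floor is given, and a value of 0 is written as listed at 0.

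Names came from a table of RefSeq genes of the assembly Zm-B73-REFERENCE-NAM-5.0, matched on gene IDs. Of the IDs, 19059 matched, 521 of them to more than 1 gene of the table, and 2709 had an informative name. A symbol not starting with LOC or a gene name among the synonyms counted as informative, and clone and marker names were left out by a pattern made after the table was seen. Coordinates are those the authors deposited, and whether their start counts from 0 or 1 was not stated.

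Before the data were examined, 26 gene lists were fixed. They cover histone deacetylases, DNA methylation and small RNA pathway, core and linker histones, DNA replication, mitotic cell cycle, meiosis, tapetum and pollen wall, pollen maturation and pollen tube, lignin and secondary wall, flavonoid and anthocyanin synthesis, photosynthesis, cytosolic ribosomal proteins, ribosome biogenesis, ribosomal RNA genes, heat shock proteins, jasmonate, MADS-box factors, inflorescence and meristem regulators, starch synthesis, seed storage, transposons, cell death proteases, organelle-encoded genes, glutathione transferases and oxidative stress, lipid transfer proteins, and sugar transport and invertases. The name table has no descriptions, so members were found by symbol and synonym alone, and 10 members shared only a symbol with the intended gene or had an ID that the table also gives to another gene. They were kept, and left out in an alternative. For the 15 lists with at least 5 tested members, the median difference was placed among the medians of 10000 random lists of the same size, each member replaced by a gene drawn from the 200 nearest in mean expression. A list outside the central 95% is called outside. This describes the 4 values per gene and is not a test.

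Named genes followed a rule fixed beforehand: HDA108; among genes past the size rule with an informative name and at least 5 FPKM in the higher group, the 6 with the largest positive and the 6 with the largest negative difference (3 and 3 in the fifth comparison); and 2 named members of each list outside the central range, except in the fifth comparison. With no p-value, the 2 members were those with the largest difference in either direction, and the part of the rule on non-overlapping libraries could not be applied. The organelle-encoded list gave no such gene. Other genes in the text are list members given as examples, chosen after their values were seen.

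Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data, with an assumed random noise, built from the 15717 genes with at least 5 FPKM in WT post-meiotic anthers, for the post-meiotic genotype comparison. The size rule found 98% of genes made 8-fold higher and 86% of those made 8-fold lower, 100% and 98% at 16-fold, and 0% of unchanged genes. The 0% follows from the small noise assumed and is not a rate of false calls in the data. Replicate noise there is unknown, and genes under 5 FPKM and differences in scaling were not simulated. A list of 8-fold higher genes lay at percentile 100, and 96 of 100 unchanged lists lay inside the central range.

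Alternatives were a pseudocount of 0.1 or 5, no filter, a filter at 5 FPKM, rescaling of each group to a sum of 1000000 (TPM), and quantile normalization. A 2-fold size rule, leaving out loci under 300 bp, random lists not matched on expression, leaving out members that share only a symbol, quantile normalization for HDA108, and a list of defence genes with and without the genes that prompted it were added after seeing the data.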

Results

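RNA was measured in anthers, the pollen-bearing organs of the tassel, of field-grown maize (Zea mays). Wild-type (WT) plants were compared with plants homozygous for a mutation in the histone deacetylase gene HDA108 (hda108), of an enzyme family that removes acetyl groups from histones. Anthers were collected after meiosis (post-meiotic) and at the mitotic stage, which gave 4 groups of 2 libraries, each library from anthers pooled over several tassels. The deposited values hold 1 FPKM (mapped fragments scaled to transcript length and to library size) per gene and group. No spread between replicates could therefore be computed, none of the differences below has a replicate check, and the words higher and lower describe these 4 values alone. A gene was counted as higher or lower when log2(FPKM + 1) differed by at least 2, a 4-fold difference for abundant genes, and folds are ratios of FPKM.

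The values covered 39604 genes, of which 24360 reached 1 FPKM in at least 1 group and entered the comparisons. Sequencing depth was unknown. The FPKM summed to 1069800 in WT post-meiotic anthers, 701133 in hda108 post-meiotic anthers, 1284190 in WT mitotic anthers and 505427 in hda108 mitotic anthers. WT anthers had 138 genes at 1000 FPKM or more after meiosis and 197 at the mitotic stage, against 38 and 22 in hda108. Rescaling every group to a sum of 1000000 moved the median genotype difference of all genes from -0.03 to 0.50 log2 after meiosis and from -0.02 to 1.05 at the mitotic stage, so counts after rescaling are given beside the main ones.

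The mutated gene itself, HDA108 (GRMZM2G136067, chromosome 4, 65983217 to 65988818, B73 RefGen_v3), was measured first. It had 12.3 FPKM in WT and 4.10 FPKM in hda108 post-meiotic anthers, 3.01-fold lower in the mutant. In mitotic anthers it had 6.43 FPKM in WT and 4.30 FPKM in hda108, 1.5-fold lower, with a log2 difference of -0.49 that turned to 0.66 after rescaling. Where the mutation lies in the gene was not known, so these values check the genotype labels only weakly. The 5 other named histone deacetylase genes were all above WT in hda108 at both stages, with 0 members past the 4-fold rule. The family median was 0.18 log2 after meiosis and 0.68 at the mitotic stage. It lay inside the central 95% of expression-matched random lists, at percentiles 78.9 and 94.5. After rescaling it was 0.77 and 1.92, against 0.50 and 1.05 for all genes. Of the 5 other genes, hda106 (GRMZM2G057044) had the largest ratio, 5.59-fold at the mitotic stage, from 0.528 to 2.95 FPKM. hda101 (GRMZM2G172883), the most abundant, had 30.1 and 33.5 FPKM in WT and hda108 post-meiotic anthers and 23.6 and 32.0 FPKM in mitotic anthers.

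The first comparison asked how the hda108 mutation altered RNA levels in post-meiotic anthers. Genes of chitinases, glucanases and other defence proteins were among the named genes with the largest positive differences. The chitinase gene chiA (GRMZM2G051943, chromosome 2, 34162587 to 34163936) had 22.8 FPKM in WT and 2928 FPKM in hda108, 128-fold higher. The glucanase gene geb1 (GRMZM2G065585, chromosome 3, 152010336 to 152011716) went from 0.361 to 119 FPKM, and the wound-inducible proteinase inhibitor gene wip1 (GRMZM2G156632, chromosome 8, 12275984 to 12276693) from 9.48 to 789 FPKM. Gns1, another glucanase gene, was 71.3-fold higher, sip1, also named Zlp, 87.4-fold higher, and the alpha-galactosidase gene AGA1 60.4-fold higher at 1051 FPKM in the mutant.

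On the lower side of the same comparison, PCP (GRMZM2G072448, chromosome 1, 75210847 to 75212440) had 5236 FPKM in WT and 177 FPKM in hda108, 29.6-fold lower. CNR3, of the cell number regulator family, was 182-fold lower, with 86.2 FPKM in WT and 0.473 FPKM in the mutant. MST2 was 44.8-fold lower and Bk2L5, a relative of brittle stalk, 82.7-fold lower. R-S, the anthocyanin regulator r1, had 168 FPKM in WT and 6.72 FPKM in hda108. MIR171g, a microRNA precursor, had 86.5 FPKM in WT and was listed at 0 in the other 3 groups.

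Of the 16 members of the pollen maturation and pollen tube list, 9 were lower in hda108 post-meiotic anthers by the 4-fold rule and 0 were higher. The list median of -2.12 log2 lay at percentile 0.75 of random lists matched on expression. Members were matched by symbol, and not each need be a pollen gene. The member abp1 (GRMZM2G116204) is also named Aux311, and the ID GRMZM2G028594 is also given to another gene. Both were above WT. The beta-expansin gene EXPB10 had 1421 FPKM in WT and 178 FPKM in hda108, and ABP2, an actin-depolymerizing factor gene, 476 and 62.7 FPKM. mgs1 had 5076 and 833 FPKM. The list median was -1.51 after rescaling, against the 0.50 of all genes, and -1.06 with quantile normalization, at percentile 2.26. Of the photosynthesis list, a marker of green tissue, 5 of 6 members were above WT in hda108, with 0 past the 4-fold rule and a median of 0.45 log2 at percentile 98.3, which was 1.03 after rescaling. Its members rca1, rubisco activase, and ME1, an NADP-malic enzyme gene, were 2.11-fold and 2.35-fold higher.

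The other lists lay inside the central 95% of random lists in post-meiotic anthers. DNA replication genes had a median of 0.33 log2, inflorescence and meristem regulators 0.10, jasmonate genes 0.09 and flavonoid genes 0.01, or 0.81, 0.52, 0.68 and 0.45 after rescaling. Tapetum and pollen wall genes, 1 of which is an aquaporin gene that shares only a symbol with the intended gene, had a median of -0.66, and sugar transport and invertase genes -0.81, which shrank to -0.11 and -0.24 after rescaling. The medians of starch synthesis (-0.34), organelle-encoded (-0.21), MADS-box (-0.08), meiosis (-0.08), glutathione transferase (-0.05) and DNA methylation and small RNA genes (-0.02) were below 0 and turned positive after rescaling. Single members departed from their lists: the lipoxygenase genes lox10 and lox1 were 53.2-fold and 26.2-fold higher, bif1 (GRMZM2G130953) was 7.33-fold lower and the MADS-box gene ZAG5 49.1-fold lower. Those 4 genes were chosen after their values were seen.

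In all, 410 genes were higher and 1090 lower in hda108 post-meiotic anthers, and 825 were higher and 661 lower after rescaling. The lower genes were concentrated among abundant RNAs. Of the 106 genes with a mean of at least 1000 FPKM over the groups, 74 were lower and 1 was higher, with a median of -2.40 log2 and of -1.79 after rescaling. The photosynthesis median lay inside the central range against random lists not matched on expression, at percentile 95.6, and with quantile normalization, at percentile 96.0, and it stayed outside without Pep1 (GRMZM5G899080), which shares only a symbol with the intended gene. The sugar list lay outside it in those same settings, at percentiles 1.89 and 1.91.

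The second comparison asked the same question in mitotic anthers. The homeodomain gene gt1, grassy tillers1 (GRMZM2G005624, chromosome 1, 23240103 to 23249045), had 2.01 FPKM in WT and 83.4 FPKM in hda108, 41.5-fold higher. The ribosome-inactivating protein gene rip2 (GRMZM2G119705, chromosome 7, 162849639 to 162851038) was 35.0-fold higher, the potassium transporter gene HAK5 49.1-fold higher and bZIP113 67.6-fold higher. PR-5, a pathogenesis-related gene, went from 0.0841 to 19.8 FPKM. AGA1 was again high, at 1006 FPKM in hda108 against 38.5 FPKM in WT.

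FIP1 (GRMZM2G046782, chromosome 10, 132115901 to 132117377) had the largest negative difference among named genes in mitotic anthers, with 497 FPKM in WT and 9.37 FPKM in hda108, 53.0-fold lower. The abscisic acid synthesis gene vp14 had 70.1 and 2.63 FPKM, and CYP88A1, the gibberellin synthesis gene dwarf3, 64.2 and 2.67 FPKM. AGA3b was 31.3-fold lower, stk1 19.1-fold lower and ATPP2-B1 37.9-fold lower.

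Of 12 tested flavonoid and anthocyanin genes, 3 were lower in hda108 mitotic anthers by the 4-fold rule, 0 were higher and 4 were above WT by less. The list median of -1.14 log2 lay at percentile 0.59, and it was -0.22 after rescaling, against the 1.05 of all genes. The chalcone isomerase gene chi1 had 1297 FPKM in WT and 90.9 FPKM in hda108, and bronze1, a flavonoid glucosyltransferase gene, 35.2 and 2.11 FPKM. Sugar transport and invertase genes had a median of -1.52 log2 at percentile 2.03, or -0.30 after rescaling, with 3 of 6 members lower and 1, incw1, higher. The soluble invertase genes IVR1 and ivr2 were 8.62-fold and 7.18-fold lower, which after rescaling came to -1.75 and -1.48 log2, short of the 4-fold rule. The list lay at percentile 2.68 with a pseudocount of 0.1.

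Of 71 tested genes encoded in the mitochondrion and plastid, 66 were above WT in hda108 mitotic anthers, 0 of them by the 4-fold rule and 32 by the 2-fold rule that was added later. The list median of 0.94 log2 lay at percentile 100, and it was 2.26 after rescaling and 1.53 with quantile normalization. Mitochondrial genes held 0.820% of the FPKM sum in WT and 2.69% in hda108, and plastid genes 0.147% and 0.572%. Pollen genes were again low, with 6 of 16 members lower, 0 higher and a median of -1.85 log2. That median lay at percentile 14.3 of expression-matched random lists, inside the central range, and at percentile 0 of unmatched ones, and it was -0.51 after rescaling and -0.026 with quantile normalization. The photosynthesis list had a median of 0.46 log2, or 1.79 after rescaling, inside the range at percentile 97.4 and outside it at 97.52 without Pep1, 99.2 after rescaling and 99.8 with quantile normalization.

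Mitotic anthers had 371 genes higher and 1979 lower in hda108. After rescaling the split turned to 3363 higher and 599 lower, and with quantile normalization it was 519 and 1284. The histone deacetylase and MADS-box lists lay outside the range with quantile normalization, at percentiles 98.4 and 98.0, the latter with a median that turned from -0.16 to 0.70 log2, and to 0.99 after rescaling. Of the 106 most abundant genes 81 were lower, with a median of -2.68 log2 and of -1.33 after rescaling.

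**Figure D1:**
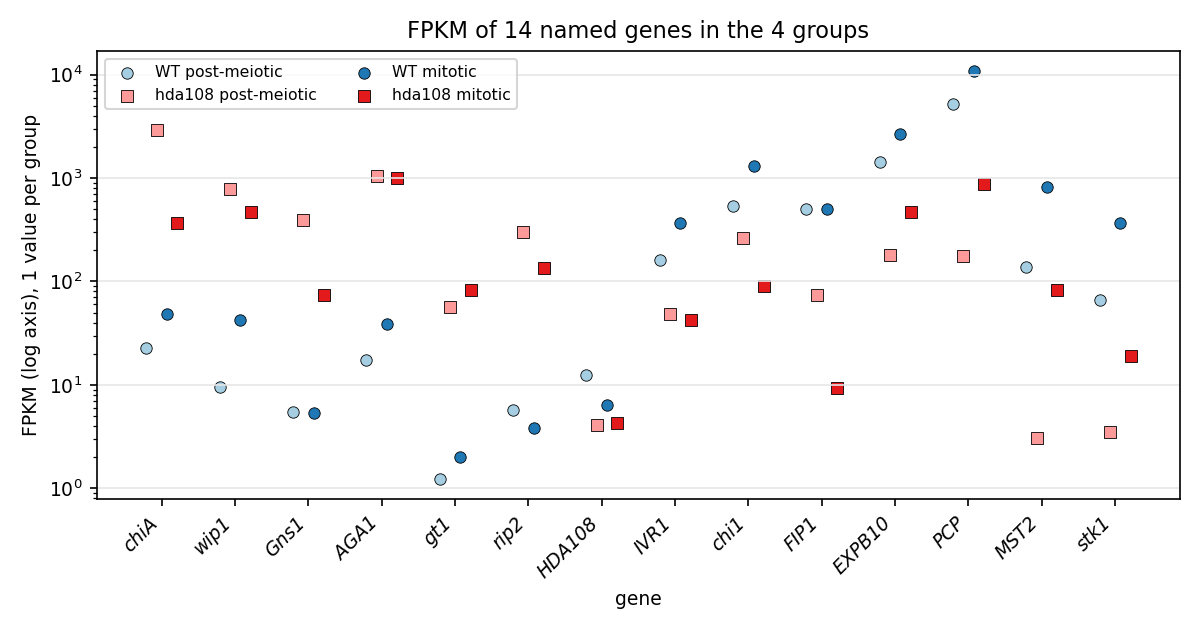
FPKM on a log axis of 14 named genes in the 4 groups, circles for WT and squares for hda108, with 1 deposited value per group and no error bars. chiA reached 2928 FPKM in hda108 post-meiotic anthers against 22.8 FPKM in WT, while PCP was at 5236 FPKM in WT and 177 FPKM in hda108.

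The genes that differed between genotypes were compared between the 2 stages, which have no library in common. The 176 shared higher genes made up 42.9% of those after meiosis and 47.4% of those at the mitotic stage, where independent lists of these sizes would share 6.24. The 870 shared lower genes, against 88.6, made up 79.8% and 44.0%. Both expected numbers take every gene as equally likely to be called. Among genes with a mean of at least 1000 FPKM, however, 69.8% and 76.4% were lower at the 2 stages. At a mean of 1 to 10 FPKM the shares were 1.42% and 3.39%. Abundance alone would thus give more than 88.6 shared lower genes, and no expected number matched on abundance was computed. chiA, geb1, wip1, Gns1, sip1, AGA1, gt1 and rip2 were among the shared higher genes, and CNR3, MST2, Bk2L5, PCP, FIP1, stk1 and EXPB10 among the shared lower ones. Across genes, which are not independent replicates, the differences at the 2 stages had a Pearson r of 0.758. GRMZM2G051898 alone was higher after meiosis and lower at the mitotic stage, and 4 genes went the other way: MIR2118d, GRMZM2G002815, GRMZM2G410865 and GRMZM5G873249. After rescaling, 512 higher genes were shared, from longer lists of 825 after meiosis and 3363 at the mitotic stage. The 328 shared lower genes then came from lists of 661 and 599.

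**Figure D2:**
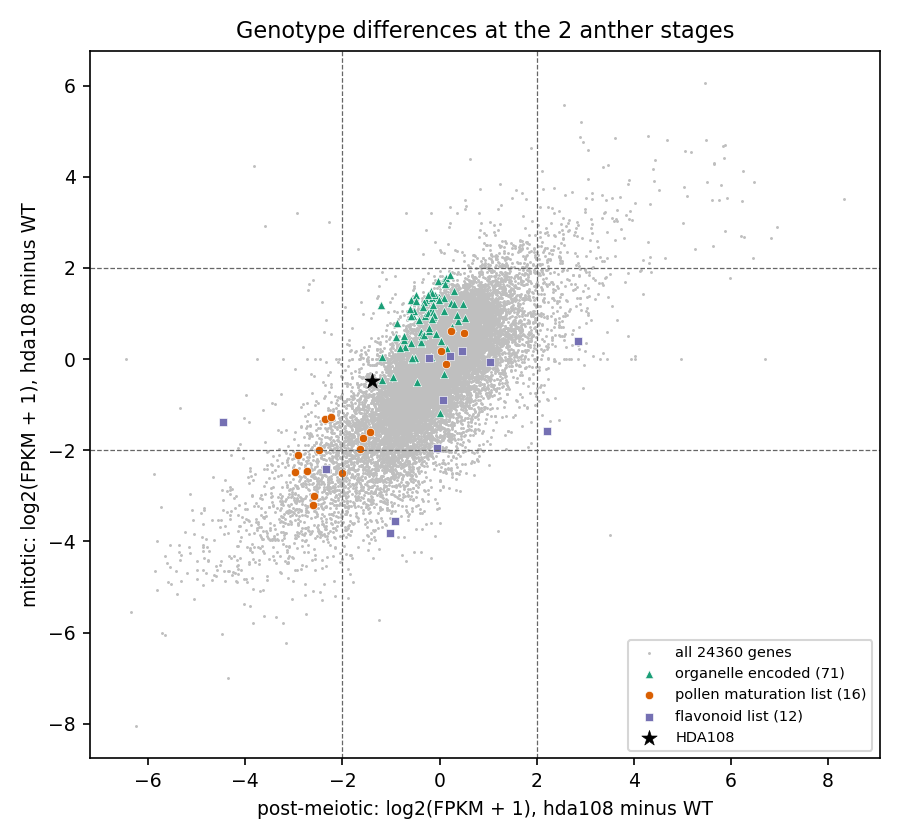
Difference in log2(FPKM + 1), hda108 minus WT, of 24360 genes in post-meiotic anthers (x axis) and mitotic anthers (y axis), with dashed lines at the 4-fold rule. Colours mark organelle-encoded genes (71), pollen maturation genes (16) and flavonoid genes (12), and a star marks HDA108; 870 genes lie in the lower left corner and 176 in the upper right.

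The third comparison asked what differed between the stages in WT anthers. Dwf4, a brassinosteroid synthesis gene (GRMZM2G065635, chromosome 1, 30536284 to 30542652), had 2.94 FPKM after meiosis and 28 FPKM at the mitotic stage. The yellow stripe-like transporter gene ysl17 was 9.47-fold higher at the mitotic stage, the invertase gene ivr2 7.05-fold and the MADS-box gene zmm2 7.32-fold. The cellulase gene Cel18/34 (GRMZM2G048165, chromosome 7, 142816579 to 142819685) was 19.5-fold lower at the mitotic stage, BURP2 18.3-fold lower, gla3 14.7-fold lower and pcr1 13.7-fold lower. The microRNA precursors MIR169i, from 5.36 to 114 FPKM, and MIR169k, listed at 0 and then at 11.1 FPKM, were higher, while MIR171g and MIR2118d were listed at 0 at the mitotic stage.

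All 6 tested members of the photosynthesis list were below their post-meiotic value at the mitotic stage in WT, 1 of them by the 4-fold rule, with a median of -1.05 log2 at percentile 0.57, or -1.30 after rescaling. That 1 gene, Pep1 (GRMZM5G899080, 6.89 and 0.659 FPKM), shares only a symbol with the intended gene of PEP carboxylase, and without it the list lay inside the central range, at percentile 15.1. The rubisco small subunit gene rbcS-m3 had 69.9 and 17.1 FPKM, a difference of -1.97 log2, just short of the 4-fold rule. Of 71 organelle-encoded genes, 69 were below their post-meiotic value, 3 of them by the 4-fold rule, with a median of -1.12 log2 at percentile 0, or -1.31 after rescaling. The pollen list had a median of 0.61 log2, or 0.34 after rescaling, and lay inside the central range, at percentile 95.8, as did the other lists. With quantile normalization the flavonoid, sugar and MADS-box lists lay outside it, at percentiles 98.1, 98.8 and 1.91, and against unmatched lists the pollen and sugar lists, at 100 and 97.6. Without a second gene named pac1 the flavonoid list lay at 98.2. WT anthers had 328 genes higher and 356 lower at the mitotic stage, 213 and 464 after rescaling, and 317 and 214 with quantile normalization. HDA108 was 1.92-fold lower at the mitotic stage.

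The fourth comparison asked the same of hda108 anthers. CNR3 had 0.473 FPKM after meiosis and 67.7 FPKM at the mitotic stage, 143-fold higher. MST2 was 26.8-fold higher at the mitotic stage, Bk2L5 23.6-fold and ARGOS9 13.1-fold. The chlorophyll-binding protein gene cab48 (GRMZM2G120619, chromosome 3, 223440714 to 223442102) had 23.2 and 0.110 FPKM, the amylase gene Amy2 679 and 30.8 FPKM, BURP2 1684 and 48.9 FPKM, and geb1 119 and 4.79 FPKM. MIR156j and MIR167d had 30.4 and 15.3 FPKM after meiosis and were listed at 0 at the mitotic stage, and MIR169i and MIR2118d had 17.2 and 6.59 FPKM at the mitotic stage after being listed at 0.

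Of the tapetum and pollen wall genes, 2 of 6 tested members were lower at the mitotic stage in hda108 by the 4-fold rule, with a list median of -1.13 log2 at percentile 0.80, or -0.94 after rescaling. The bHLH gene ms23 had 21.8 and 3.0 FPKM and ms8 7.02 and 0.474 FPKM. Flavonoid genes had 2 of 12 members lower and a median of -1.10 log2 at percentile 0.20, or -0.94 after rescaling, with the chalcone synthase gene c2 at 25.9 and 3.27 FPKM and bronze1 at 14.5 and 2.11 FPKM. Jasmonate genes had 2 of 8 members lower and a median of -1.06 log2 at percentile 0.96, or -0.60 after rescaling, with ts1, a lipoxygenase gene of jasmonate synthesis, at 164 and 22.6 FPKM and ts2 at 35.3 and 5.93 FPKM. Organelle-encoded genes had a median of 0.07 log2, which lay at percentile 99.99, above the central range of random medians of -0.48 to -0.09, and which was 0.47 after rescaling.

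In hda108, 248 genes were higher and 715 lower at the mitotic stage, 466 and 466 after rescaling, and 450 and 518 with quantile normalization. HDA108 differed by 1.05-fold. With quantile normalization the jasmonate list lay inside the range, at percentile 3.65, and the starch list outside it, at 98.95, as was the pollen list against unmatched lists, at 99.98. Of the genes higher at the mitotic stage, 132 were shared by both genotypes against 3.34 for independent lists. Of the lower genes, 162 were shared against 10.4. These expected numbers, too, take every gene as equally likely to be called, and none matched on abundance was computed. The Pearson r of the stage differences across genes was 0.510.

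The fifth comparison took the genotype difference at the mitotic stage minus that after meiosis. Flavonoid genes had a lower genotype difference at the mitotic stage than after meiosis, with a median of -1.04 log2 at percentile 0.02, or -0.98 after rescaling, and 4 of 12 tested members lower and 1 higher by the 4-fold rule. Jasmonate genes had a median of -0.86 at percentile 0.88, or -0.14 after rescaling, and sugar transport and invertase genes -0.89 at percentile 1.94, or -0.25. Organelle-encoded genes had a median of 1.15 at percentile 100, or 1.89 after rescaling, with 68 of 71 members above 0 and 1 past the 4-fold rule, and pollen genes 0.11 at percentile 98.7, with medians of 0.84 after rescaling and 0.85 with quantile normalization; the percentile was 69.5 against unmatched random lists and 95.1 with quantile normalization, both inside the range. Among single genes, CNR3 had a value of 3.35 log2, geb1 -4.25 and chiA -4.05. The microRNA precursors MIR2118d (6.51), MIR171g (6.45) and MIR156j (-4.97) had the largest values of named genes. HDA108 had a value of 0.90 log2. In this comparison 103 genes were higher and 495 lower, 370 and 224 after rescaling, and 193 and 430 with quantile normalization. Lists inside the range that left it were those of meiosis, at percentiles of 97.7 to 98.5 in 3 settings, histone deacetylases at 97.9 with a pseudocount of 0.1, tapetum at 2.35 after rescaling and starch at 98.3 with quantile normalization.

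**Figure D3:**
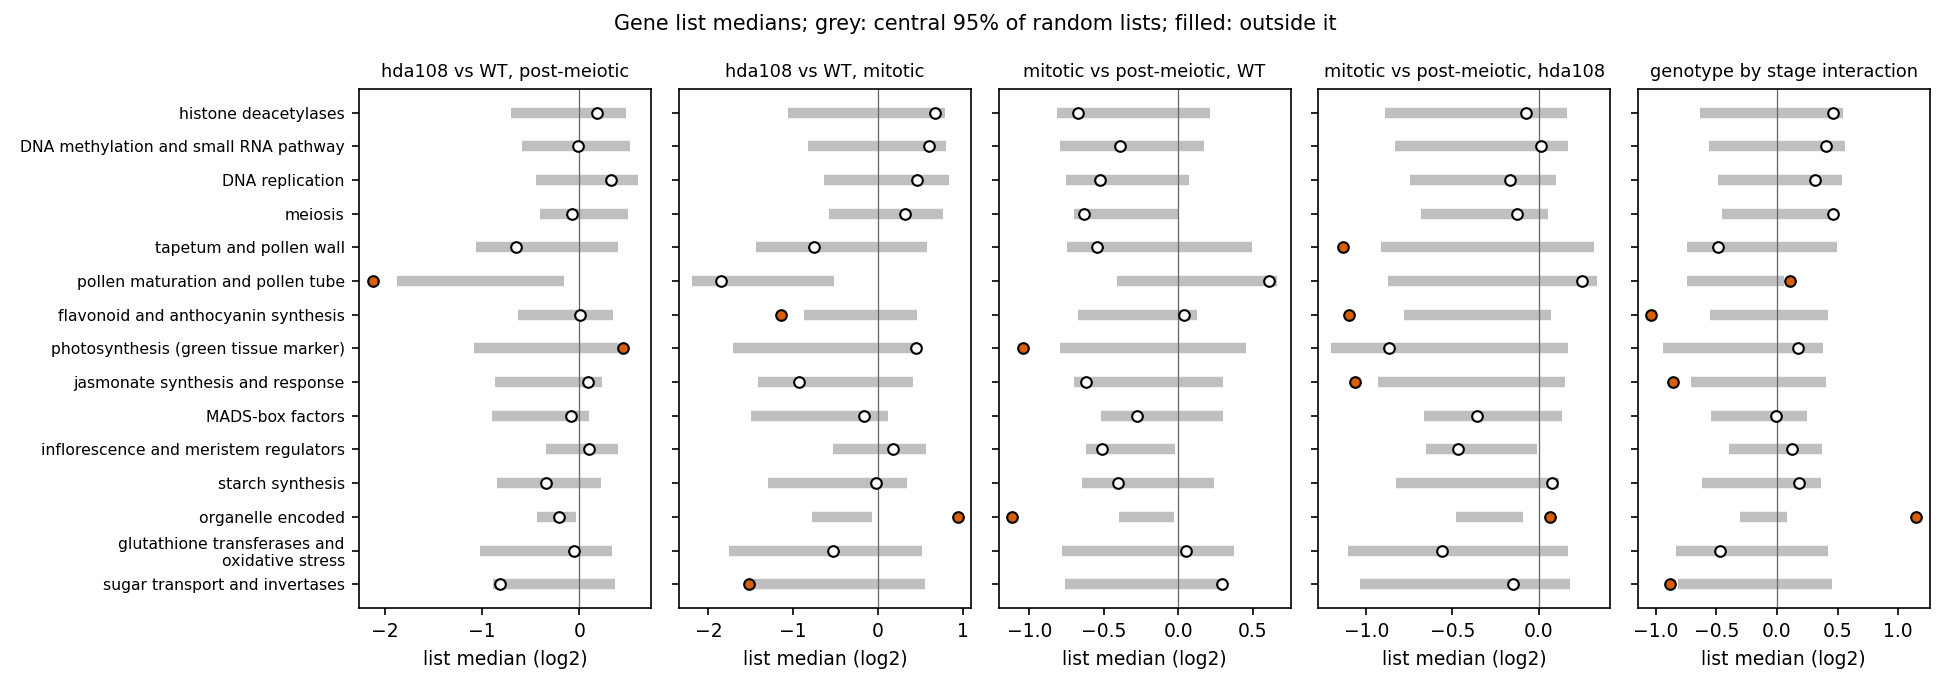
Median log2 difference of each of the 15 gene lists (circles) in the 5 comparisons, one per panel, with the central 95% of medians of 10000 random expression-matched lists as grey bars; filled circles lie outside it. The pollen list lies at -2.12 in post-meiotic anthers and the organelle-encoded list at 0.94 in mitotic anthers.

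Some lists held fewer than 5 tested members and were not set against random lists: lignin and secondary wall (4), heat shock proteins (4), seed storage (3), cell death proteases (3), core and linker histones (2), cytosolic ribosomal proteins (2), and mitotic cell cycle, ribosome biogenesis, ribosomal RNA, transposon and lipid transfer genes (0 each). The seed storage member ole1 had 107 and 27.4 FPKM in WT and hda108 post-meiotic anthers, and the cell death protease gene mir1 had 114 and 12.8 FPKM in mitotic anthers. Both were picked after their values were seen. The loci of MIR171g, MIR2118d, MIR167d, MIR156j and MIR169i span under 300 bp, so a few fragments can set their FPKM.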

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

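The results in this part had genotype or stage effects of opposite direction in the 2 stages or the 2 genotypes, of at least 2-fold on the log2(FPKM + 1) scale for reported genes and at least 4-fold for any other gene. With 1 value per group, none of these differences between groups was tested.

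The flavanone 3-hydroxylase gene f3h (GRMZM2G062396) was above WT in hda108 post-meiotic anthers, by 2.21 log2, and below it in mitotic anthers, with a difference of -1.59. Between stages it differed by 1.99 in WT and -1.81 in hda108. Another flavonoid gene, chi1, had stage differences of 1.26 log2 in WT and -1.54 in hda108, and the regulator R-S had -1.12 and 1.95. The abscisic acid synthesis gene vp14 had 1.43 and -1.05, and the chitinase gene chiA 1.07 and -2.98.

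The microRNA precursor MIR2118d had genotype differences of -3.59 log2 after meiosis and 2.92 at the mitotic stage, and stage differences of -3.59 in WT and 2.92 in hda108, with 11 FPKM in WT post-meiotic anthers, 6.59 FPKM in hda108 mitotic anthers and 0 listed in the other 2 groups. GRMZM5G873249 had genotype differences of -3.82 and 4.24 and the same stage differences, also with 0 listed in the other 2 groups. These 2 loci span 148 and 249 bp. GRMZM2G051898 had genotype differences of 3.52 and -3.85 log2 and stage differences of 3.94 in WT and -3.43 in hda108. GRMZM2G410865 had genotype differences of -2.28 and 3.02 and stage differences of -2.85 and 2.45. GRMZM2G002815 had genotype differences of -2.93 and 3.21.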

How the results depend on the processing

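No paired analysis was possible because the values carry 1 column per group and no replicate number. For the same reason leaving out single libraries, replicate weights, other variance models, an adjusted p with a fold minimum, fits on fewer libraries, camera with an estimated correlation and fry could not be run. Nothing here measures error between replicates, and unknown depth limits every low value. The 2-fold size rule, unmatched random lists, short loci, shared symbols and quantile normalization of HDA108 were chosen after seeing the data.

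Gene counts follow in the order of the comparisons, post-meiotic genotype, mitotic genotype, WT stage, hda108 stage and the fifth. A pseudocount of 0.1 gave 1114, 1189, 574, 430 and 496 higher genes, and 1048, 1641 and 1142 lower genes in the last 3. A pseudocount of 5 gave 131, 107, 209, 95 and 24 higher and 666, 1225, 126, 291 and 178 lower genes, as built, since it shrinks differences of low genes. Rescaling to 1000000 gave 825, 3363, 213, 466 and 370 higher genes, and 661, 599, 466 and 224 lower genes in all but the WT stage comparison, where 464 were lower. It shifted the median of all genes to 0.50, 1.05, -0.51, 0.11 and 0.60 log2. Quantile normalization gave 1284 lower genes in the mitotic genotype and 214 in the WT stage comparison, and 450 and 193 higher genes in the last 2. The 2-fold rule gave 1809, 2541, 1403, 831 and 1141 higher and 3149, 5063, 2757, 3805 and 2769 lower genes, by its construction. Counts with no filter, with a filter at 5 FPKM and without loci under 300 bp were within 1.5 times the main ones.

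The higher genes shared by the stages were 568 with a pseudocount of 0.1 and 512 after rescaling, and the lower ones 328 after rescaling and 523 with quantile normalization. Lists outside the central range were 6 instead of 3 in the mitotic genotype comparison and 5 instead of 2 in the WT stage comparison with quantile normalization, and 4 in the latter against unmatched lists. Of 75 placements of a list, 72 kept their side of the range with a pseudocount of 0.1, 73 after rescaling, 62 with quantile normalization, 67 against unmatched lists and 72 without members that share only a symbol. The 3 that then changed side were the photosynthesis list at the mitotic stage, from inside to percentile 97.52, and in the WT stage comparison the photosynthesis list, from outside to percentile 15.1, and the flavonoid list, from inside to percentile 98.2. No list outside the range in the main analysis had a median of the opposite sign under these settings. The MADS-box list of the mitotic genotype comparison, which left the range with quantile normalization, turned from a median of -0.16 to 0.70 log2, and to 0.99 after rescaling, inside the range. The cause of the other shifts was not tested.

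For HDA108, a pseudocount of 0.1 gave log2 values of -1.56, -0.57, -0.93, 0.066 and 0.996 in the 5 comparisons, rescaling -0.87, 0.66, -1.06, 0.47 and 1.53, and quantile normalization -1.37, -0.51, -0.45, 0.41 and 0.86. The mitotic genotype value thus reversed under rescaling. Of named genes, 69 of 70 values kept their side of the 4-fold rule with a pseudocount of 0.1 and 67 of 70 after rescaling.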

Other observations

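Except for the test on less abundant genes of chromosome 4, the tests in this part were chosen after the results they bear on were seen.

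A list of 16 defence names was made after the largest differences were seen and so restates them in part. It matched 12 tested genes of chitinases, glucanases, proteinase inhibitors and pathogenesis-related proteins. After meiosis 12 of 12 were higher by the 4-fold rule, with a median of 4.43 log2, and at the mitotic stage 9 of 12, with a median of 2.85. Without the 6 members that were among the named genes with the largest positive differences, 6 of 6 were higher after meiosis, with a median of 3.16 log2, and 3 of 6 at the mitotic stage, where all 6 were above WT and the median was 2.0; these names, too, were written after values were seen. The chitinase gene chn1 had 17.7 and 604 FPKM in WT and hda108 post-meiotic anthers, the proteinase inhibitor gene MPI 12.9 and 135 FPKM, and PR10 3.82 and 22.0 FPKM. The lipoxygenase genes lox1 and lox10 had 4.24 and 1.76 FPKM in WT and 111 and 93.8 FPKM in hda108 post-meiotic anthers. Within hda108 the list was lower at the mitotic stage, with a median of -1.47 log2, while in WT it was 0.04. Because the list was chosen in part for high values in hda108 post-meiotic anthers, that choice favours such a fall.

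A loss of abundant pollen RNA that lifted the share of all other genes alike is argued against as the whole source of the defence pattern by genes not chosen for it: the 24332 tested genes outside the pollen and defence lists had upper quartiles of 0.36 log2 after meiosis and 0.57 at the mitotic stage, or 0.88 and 1.68 after rescaling, and every defence gene, though chosen for high values, lay above these, the lowest at 2.26 and 1.34, or 2.83 and 2.04 after rescaling. Mature leaf tissue in the mutant samples stays open because the level of chiA in leaves is not known. Of the FPKM that chiA gained, rca1 gained 4.96% after meiosis and 14.6% at the mitotic stage, and mdh6 -0.848% and 10.2%. C4ppdkZm1 gained 0.276% and 8.28%, and rbcS-m3 0.973% and 0.645%. The low values of pep1 (GRMZM2G083841) were below WT, at 0.183 and 0.136 FPKM in WT and hda108 after meiosis and 0.289 and 0.0491 at the mitotic stage. ME1 was at 3.39 FPKM or less in the mutant groups. Other green tissue, unequal exposure of the field-grown plants to wounding or pathogens, and an effect of the mutation itself may each be involved, and none was tested.

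The pollen list had a median below 0 in hda108 against WT at both stages, at the mitotic stage within the range of expression-matched random lists. A single scaling factor acts on every gene alike, whereas the pollen list median minus that of all genes was -1.83 log2 at the mitotic stage and -2.09 after meiosis; quantile normalization, which acts by abundance, left list medians of -0.026 and -1.06, so an abundance-dependent shift stays open, above all at the mitotic stage. A smaller share of pollen in the mutant anthers cannot be told apart from lower expression per pollen grain. The green tissue and tapetum medians, without members that share only a symbol, lay 1.12 log2 apart after meiosis and 0.73 at the mitotic stage. Both distances were less than the 2.25 and 2.38 that their members' quartiles span. Mutant anthers younger than WT anthers of the same stage could give the low values of the 132 genes that were higher at the mitotic stage in both genotypes, whose median genotype difference was -3.99 after meiosis and -3.75 at the mitotic stage. They should also hold more RNA of the 162 genes that were lower at the mitotic stage in both, and those had medians of -0.16 and -0.02 with quartiles on both sides of 0, so age stays open.

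Of 10 genes with at least 5 FPKM in both WT groups and under 0.5 FPKM in both mutant groups, 8 were on chromosome 4, which carries HDA108, among them GRMZM2G495171 (82061216 to 82062221; 49.7 and 65.7 FPKM in WT, 0 listed in hda108), where expression-matched random sets had 0.977 on average and at most 6. A lower depth of the mutant libraries would spread such genes over chromosomes, and hda108 had fewer genes listed at 0 (8719 and 9086) than WT (10100 and 10905). A sequence difference linked to the hda108 locus, such as a chromosome segment from another strain, is a candidate explanation for the excess on this chromosome. A second set of 55 genes near 0 in hda108, not used to notice the pattern, had at least 1 FPKM in both WT groups and fell outside the first set. Of these, 20 (36.4%) were on chromosome 4, against 5.45 on average and 10 at the upper bound of random sets. The 8 genes spanned 61122833 to 175761094, a stretch that contains HDA108, and the 20 genes 1463947 to 210338409. Median distances from HDA108 were 98.6 and 84.8 Mb against 96.5 Mb for all tested genes of the chromosome, so the medians gave little sign of closeness. Upper quartiles of the distance were lower, at 103 and 107 Mb against 134 Mb, and lower quartiles higher, at 58.4 and 53.0 against 47.4 Mb. Distance regardless of side cannot show clustering on a single side of HDA108, which starts at 65983217, near the lower end of the stretch of the 8 genes. A linked segment would have to cover most of the chromosome to hold all 20 genes, but a shorter one could hold the 8. The segment need not hold all 20, since random sets had 5.45 genes on chromosome 4 on average. The reverse set, near 0 in WT and expressed in hda108, had 4 of 16 genes on chromosome 4, at the upper bound of 4 for random sets. Silencing of any of these genes through HDA108 was not tested.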
